A study of Mus musculus with 4 samples.

How the data were processed

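RNA was measured in 4 libraries of mouse brain from animals that carry Cre recombinase behind the cholecystokinin gene (Cck). Per the labels, 2 libraries were made from RNA pulled down with an antibody against GFP from cholecystokinin neurons, and 2 from total RNA of the dorsal raphe nucleus, a midbrain and pontine cell group. The method is translating ribosome affinity purification with a viral vector, in which a ribosomal protein tagged with GFP is made only in cells with Cre, so that ribosomes of those cells and the RNA bound to them can be pulled down. Per the labels' protocols, RNA was taken up with an Agilent Nanoprep kit, cDNA was made with the Clontech Ultra Low v4 kit and libraries were prepared with NexteraXT. The labels do not say which animals or how many gave each library, so that p-values measure only the spread between these libraries, which may be technical.

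Per the submitters' processing notes, bcl2fastq 2.19, kallisto 0.44.0 and DESeq2 were used, with a DESeq2 version not given in the sources used here. The notes name the builds GRCm38.p6 and GRCh38.p12 without saying what the human build was used for. The single table used here holds the authors' own comparison of the groups by gene symbol, and 0 of its columns give a value per library. Its mean column is a signal that the authors made as the mean normalized count over the libraries, per the file headers. Its fold change and the standard error of that fold change are on the log2 scale, as deposited. Its test statistic is a score that the authors deposited, and it equalled the fold change over its standard error to within 1.44e-07. Its p-value and adjusted p-value columns are the authors' own.

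The table has 36144 rows, of which 15064 have a mean of 0 and 21080 have a p-value. An adjusted p-value is given for 16361 genes, those with a mean normalized count from 10.12 upwards. These deposited adjusted p-values differed by at most 3.56e-07 from a Benjamini-Hochberg adjustment over the same genes. The lowest unadjusted p among the 4719 genes left out was 0.133. A date stood in place of a gene name on 26 rows, and 2 names stood on 2 rows each. Of the genes with an adjusted p-value, 16307 had their symbol in the reference's symbol table. Positions, gene types and the longest transcript per gene, found for 16282 of these genes, were taken from GENCODE M21, which is built on GRCm38.

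The direction of the deposited fold change had to be settled from the data. The header names no numerator, and the table's own name puts the immunoprecipitates before the total RNA. Read that way, Cck and the gene of the ribosomal protein usually tagged in this method, Rpl10a, would be lower in the immunoprecipitates, and glial genes higher. The sign was therefore turned throughout, so that a positive value stands for more RNA in the immunoprecipitates. The direction of Cck, Rpl10a and the glial genes is for this reason a choice and not a finding, and the direction of each other gene rests on it. That Cck and Rpl10a moved opposite to glial and mitochondrial genes holds with either sign. Libraries exchanged between the groups would look the same as a turned sign.

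With no values per library, no test of gene expression across libraries was computed here, and the quasi-likelihood test planned for counts was replaced by the plan for this case, which describes the authors' deposited table. Group means were derived from the mean and the fold change of each gene. Whole reads were visible in the lowest means: 775 of 788 genes with a mean above 0 and under 0.3 fell on 4 values when compared to 4 decimals, each the worth of 1 read in 1 library. These gave size factors of 1.11 and 1.05 for the total RNA libraries and 0.988 and 0.864 for the immunoprecipitates. A group with a derived mean under 0.35 was read as having no read. Its fold is given as a lower bound, against 3 reads over the 2 libraries of the group, which covers counting error only. With 1 to 3 reads the ratio of the derived means is given with a 95% Clopper-Pearson counting interval. That interval was computed from rounded reads not scaled by the size factors, so that it need not centre on the ratio. It covers counting error only.

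Gene lists were fixed before the data were examined, apart from 7 added lists named in the closing section. The median fold change of a list was placed as a percentile among 10000 random lists of the same size, matched on mean level in 20 bins, and a list was called where it fell outside the central 95%. Lists needed at least 3 genes with an adjusted p-value. Named genes were Cck, then in each direction the 12 genes with the largest fold among those with an adjusted p under 0.05 and a mean of at least 50, then up to 4 genes per list with the smallest adjusted p and all genes of lists of 5 or fewer. Names of predicted genes and pseudogenes were passed over, as were names missing from the symbol table; 146 genes in the higher and 44 in the lower direction passed the thresholds but not this step. The rule's condition on single libraries was not evaluated here. Genes outside the rule are named as such, and some genes that the rule names are not reported here.

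Alternatives were other filters and thresholds, and, chosen after the data were seen, folds centred on their median, a lowess trend on transcript length (span 0.3) removed, a t distribution with 2 degrees of freedom, ribosomal protein, mitochondrial and pseudogene rows left out, and random lists also matched on transcript length. The length trend was fitted on genes with a mean of at least 1000 and subtracted from all genes with a length. Standard errors were left unchanged. Spearman's rho of fold and length was -0.47 in the fitted genes and -0.28 over all, so that trend-removed values are less certain for genes of low level. The adjustment and the list test were tested on simulated data, in which 200 of the 16361 genes were changed and noise was drawn with the deposited standard errors. In the simulation, 35.0% of genes changed by a log2 fold of 1 and 75.0% of those changed by 2 were recovered, and 3.5% of calls were unchanged genes. Of 100 random lists of 12 genes, 95 fell inside the central 95%. Noise was drawn independently for each gene and these lists at random, so that a share near this was set by the design. Genes of a real list can move together, which the list percentiles do not allow for. The deposited table called 32.5% of genes, far more than were changed in the simulation, so that the recovered shares need not hold for it. As the noise followed the deposited standard errors, the simulation does not test those errors. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and the plots matplotlib.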

Results

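Ribosome-bound RNA of cholecystokinin neurons was compared with total RNA of the dorsal raphe nucleus, with 2 libraries in each group. The groups differ both in cells and in RNA fraction. Each fold therefore mixes at least enrichment in the tagged neurons and binding to ribosomes. RNA of other cells carried into the immunoprecipitates was not measured and can also enter. These parts cannot be told apart here. The mean normalized counts in the authors' deposited table summed to 59046243, the size of an average library, and genes with an adjusted p-value had a median of 974 counts. The size factors read from single-read steps ranged from 0.864 to 1.11, so that the scaling of the 4 libraries differed little. Folds below are log2 values of immunoprecipitate over total RNA ± the authors' standard error, with the deposited sign turned as set out above, a choice on which each direction rests. The calls are those of the authors' DESeq2 test, with an adjusted p under 0.05.

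Cck, the gene that drives Cre and encodes the peptide cholecystokinin (ENSMUSG00000032532.7, chromosome 9, 121489824 to 121495694 on GRCm38), stood at 5.76 ± 0.13 in the authors' deposited table. This was a 54.3-fold difference (95% interval 45.3 to 65.2), from a derived mean of 1208 normalized counts in total RNA to 65608 in the immunoprecipitates. Rpl10a, which encodes a protein of the large ribosomal subunit (chromosome 17, 28328471 to 28331033), stood at 3.87 ± 0.11 in the authors' deposited table. Its reads cannot be separated with certainty from those of the pseudogene Rpl10a-ps1, chosen after its values were seen, which stood at 4.33 ± 0.44 there (2.57 with the trend on transcript length removed). If the tagged protein of the vector is Rpl10a, its transcripts could also count here, so that 3.87 need not be the endogenous gene alone. Because the sign was set by Cck, Rpl10a and glial genes, their own directions are a choice. Only the sizes of their folds and the opposition of Cck and Rpl10a to glial genes are measurements. With that trend removed, Cck stood at 4.21.

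Across the genome the authors' deposited table called 2672 genes higher and 2653 lower in the immunoprecipitates, of 16361 tested. With a further 2-fold threshold, 1628 were higher and 1658 lower. The median fold of the tested genes was -0.10, and folds centred on it gave 2975 higher and 2249 lower genes. Folds also tended to fall with transcript length, along a fitted trend that ranged from 2.87 to -0.40 on the log2 scale, and its removal moved the values of 34 of the 128 named genes by over 1.5 times.

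Neuropeptide precursor genes were either higher in the immunoprecipitates or did not pass the test. Of 41 listed genes 34 were tested, and 18 of them were higher in the authors' deposited table, none was lower and 16 did not pass, and the same number, 18, passed when adjusted over the list alone. The list's median of 2.11 lay above all 10000 random lists of like level (percentile 100). Npw, the precursor of neuropeptide W (chromosome 17, 24657330 to 24658457), stood at 6.28 ± 0.35 in the authors' deposited table, and Vip, that of vasoactive intestinal peptide (chromosome 10, 5639218 to 5647617), at 4.99 ± 0.15. They stood at 4.5 and 4.85 with the length trend removed. Nms, which encodes neuromedin S, had no read in total RNA and was at least 93.4-fold higher in the immunoprecipitates by the authors' deposited table. That bound covers counting error only. Sst, the somatostatin gene, stood at 1.43 ± 0.13 in the authors' deposited table, and at -0.23, no longer called, with the length trend removed. With that trend removed the list's median was 0.56, with 10 genes called higher and 4 lower. Among random lists matched on level and transcript length, the median of 2.11 lay at percentile 100, with the middle list at 0.90.

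Several further peptide genes, chosen after their values were seen, had large folds with unequal precision. Cartpt, which encodes the CART peptide, stood at 6.34 ± 1.86 in the authors' deposited table with a mean of 722281 normalized counts, and its 95% interval ran from 6.47-fold to 1011-fold. Ucn, the urocortin gene, stood at 6.24 ± 0.72, Tac1, the precursor of substance P, at 2.59 ± 0.62 and Nts, the neurotensin gene, at 2.51 ± 0.34 (1.46 with the length trend removed) in the authors' deposited table. Penk at 0.27 ± 0.15, Gal at 0.15 ± 0.62, Npy at -0.38 ± 0.61 and Trh at -0.35 ± 0.49 did not pass the test in the authors' deposited table. With the length trend removed these genes stood at -0.58, -1.42, -2.28 and -1.25.

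**Figure D1:**
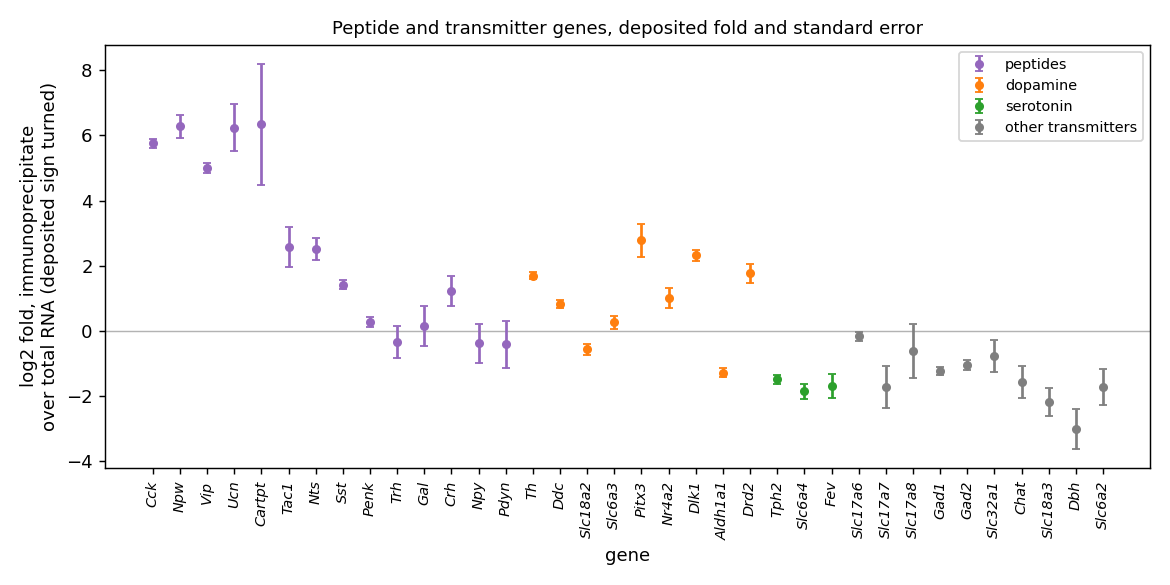
Log2 fold of immunoprecipitate over total RNA for peptide and transmitter genes (vertical axis), one point per gene (horizontal axis), with bars of 1 standard error as deposited by the authors. In the authors' deposited table Cck (5.76), Npw (6.28) and Vip (4.99) stand far above 0 with short bars (4.21, 4.5 and 4.85 with the length trend removed), Cartpt has the longest bar (1.86), and Tph2 (-1.49) and Slc6a4 (-1.85) lie below 0; with the length trend removed Sst lies at -0.23.

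Genes of dopamine neurons were mostly higher in the immunoprecipitates and genes of serotonin neurons mostly lower. Of 10 dopaminergic genes 7 were higher in the authors' deposited table, 2 were lower and 1 did not pass, the same counts as adjusted over the list alone (7 and 2), with a median of 1.21 at percentile 99.7 of random lists. Th, the rate-limiting enzyme of dopamine synthesis, stood at 1.70 ± 0.10 and Dlk1, a Notch-related membrane protein, at 2.32 ± 0.17 in the authors' deposited table, while Aldh1a1, a retinaldehyde dehydrogenase, was at -1.28 ± 0.14. Outside the naming rule, Pitx3, a transcription factor of midbrain dopamine neurons, stood at 2.78 ± 0.50 and Slc6a3, the dopamine transporter, at 0.27 ± 0.21, not called, in the authors' deposited table. Of the 12 serotonergic genes 9 were lower, 1 higher and 2 did not pass, against 9 and 2 adjusted over the list alone, with a median of -1.04 at percentile 0.05. After removal of the length trend 6 were lower and 3 higher. Tph2, the brain enzyme of serotonin synthesis, stood at -1.49 ± 0.13, Slc6a4, the serotonin transporter, at -1.85 ± 0.22, and Fev, a transcription factor of serotonin neurons, at -1.69 ± 0.38 in the authors' deposited table. Ddc, which both lists hold and which makes both transmitters, was at 0.84 ± 0.13 there, and at 0.44 with the length trend removed. Slc18a2, the vesicular monoamine transporter, is also in both lists and, outside the naming rule, was called lower in the authors' deposited table.

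Genes for other transmitters were lower or did not pass. Of 5 GABAergic and glycinergic genes 3 were lower in the authors' deposited table, also 3 adjusted over the list alone (median -1.24, percentile 0.39), with Gad1, a GABA-synthesizing enzyme, at -1.24 ± 0.12 and Gad2 at -1.04 ± 0.14 (-0.67 with the length trend removed). Of 4 cholinergic genes 3 were lower, also 3 adjusted over the list alone (median -1.53, percentile 0.18), among them Chat, which makes acetylcholine, at -1.56 ± 0.50 in the authors' deposited table. Of 4 noradrenergic genes 3 were lower, also 3 adjusted over the list alone, with Dbh, which makes noradrenaline, at -3.00 ± 0.61 in the authors' deposited table. Their median of -2.36 lay at percentile 2.7, inside the central 95%, and outside it with a stricter filter (percentile 0.17). For the 3 vesicular glutamate transporters the authors' deposited table gave Slc17a6 at -0.17 ± 0.14, which is 0.17 with the length trend removed, and Slc17a8 at -0.61 ± 0.83, which is -0.24, neither called, and Slc17a7 at -1.71 ± 0.64, lower, the 1 call adjusted over the list alone too (median -0.61, percentile 20.9; the median is -0.24 with the trend removed).

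Most glial genes moved opposite to Cck and were lower in the immunoprecipitates under the chosen sign, while 2 oligodendrocyte precursor genes moved with Cck. With that sign, all 12 astrocyte genes were lower in the authors' deposited table, as were all 12 adjusted over the list alone (median -1.67, percentile 0), for example Gja1, which encodes a gap junction protein, at -2.78 ± 0.22 and Fgfr3 at -2.69 ± 0.26. Of 12 oligodendrocyte genes 11 were lower, also 11 adjusted over the list alone (median -1.63, percentile 0), with Ermn at -2.55 ± 0.20 and Cnp, an enzyme of myelin, at -1.78 ± 0.09 in the authors' deposited table. Of 8 oligodendrocyte precursor genes 6 were lower and 2 higher, with the same counts, 6 and 2, adjusted over the list alone (median -2.10, percentile 0.01). Sox10, a transcription factor of the lineage, was at -2.24 ± 0.22, while C1ql1 at 1.70 ± 0.24 (0.88 with the length trend removed) and, outside the naming rule, Cspg4 at 1.84 ± 0.47 were higher in the authors' deposited table. Of 12 microglial genes 7 were lower and 5 did not pass, against 8 adjusted over the list alone (median -1.65, percentile 0), with Csf1r, a growth factor receptor, at -3.02 ± 0.37 and P2ry12 at -5.04 ± 1.19 in the authors' deposited table. The microglial median was -2.59 with the length trend removed, and 9 genes were called lower.

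Most vascular, ependymal and blood cell genes did not pass the test. Of 12 endothelial genes the authors' deposited table called 2 higher and 1 lower, also 2 and 1 adjusted over the list alone (median 0.45, percentile 94.3), namely Cldn5 at 1.91 ± 0.56, Ly6c1 at 1.66 ± 0.49 and Slc2a1 at -0.92 ± 0.29. With the length trend removed Cldn5 was at 1.03 and Ly6c1 at 0.17, no endothelial gene was called higher and 1 was called lower. None of 12 mural and fibroblast genes (median -0.27, percentile 48.2), 8 ependymal genes (median -0.76, percentile 16.0) and 5 red blood cell genes (median -0.28, percentile 32.9) was called in the authors' deposited table, nor, with 0 each, when adjusted over the list alone. Against random lists of like transcript length, the ependymal list (percentile 1.98) and the red blood cell list (percentile 0.55) fell below the central 95%. With the length trend removed the medians of the 3 lists were -0.63, -1.67 and -1.97, and 2 mural and fibroblast, 2 ependymal and 4 red blood cell genes were called lower and none higher.

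General neuronal genes went both ways. Of 16 tested, 5 were higher in the authors' deposited table, 7 lower and 4 did not pass, also 5 and 7 adjusted over the list alone (median -0.07, percentile 6.32; the median is 0.03 with centred folds and 0.01 with the length trend removed). Uchl1, a ubiquitin hydrolase of neurons, stood at 1.31 ± 0.09, which is 0.20 and not called with the length trend removed, while Nefl, a neurofilament subunit, stood at -1.27 ± 0.08 and Syn1, a synaptic vesicle protein, at -1.45 ± 0.12 in the authors' deposited table.

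**Figure D2:**
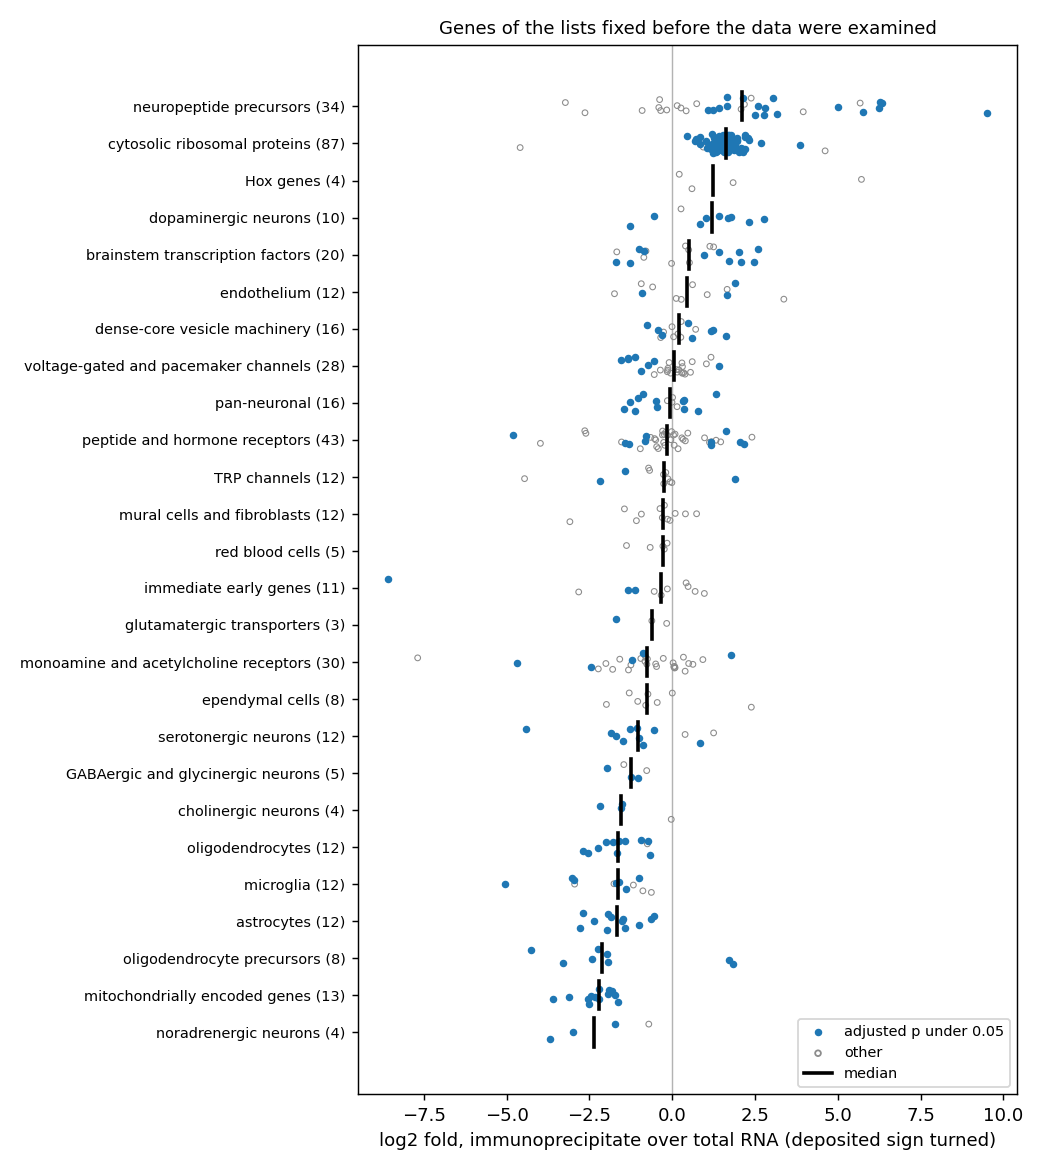
Log2 fold of immunoprecipitate over total RNA (horizontal axis) for each tested gene of the lists fixed before the data were examined (rows, with the number of tested genes), from the authors' deposited table. Filled points have an adjusted p under 0.05, bars mark list medians, and fitted folds are drawn for genes with no read in a group. The neuropeptide precursors have a median of 2.11, which is 0.56 with the length trend removed, and the astrocyte, oligodendrocyte and mitochondrially encoded lists (medians -1.67, -1.63 and -2.22, the last -3.62 with the trend removed) lie below 0; the pan-neuronal median of -0.07 turns to 0.03 with centred folds.

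Transcription factors of the brainstem went both ways. Of 20 tested, the authors' deposited table called 7 higher and 4 lower, against 8 and 4 adjusted over the list alone, with a median of 0.51 at percentile 99.3. After removal of the length trend the median was 0.82, with 9 called higher and 2 lower. En1, which patterns the midbrain and anterior hindbrain, stood at 2.48 ± 0.26, its relative En2 at 0.96 ± 0.27 and Foxa2, a floor plate factor, at 2.02 ± 0.50 in the authors' deposited table, while Fev was lower as given above. Of 39 Hox genes, which pattern the hindbrain and spinal cord, 4 were tested, all with means under 50, and 0 were called, also 0 adjusted over the list alone (median 1.22, percentile 89.9). These were Hoxc4 at 0.21 ± 3.22, Hoxd1 at 0.60 ± 3.65, Hoxd11 at 1.84 ± 3.31 and Hoxd13 in the authors' deposited table, the last with a ratio of 52.5 whose counting interval runs from 16.8 to 245. That interval is of unscaled reads and leaves out the spread between libraries. With the length trend removed Hoxc4 was at -0.12 and Hoxd1 at 0.10.

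Genes of the machinery of peptide release went both ways. Of 16 dense-core vesicle genes the authors' deposited table called 5 higher and 3 lower, against 6 and 3 adjusted over the list alone (median 0.22, percentile 47.1), and 7 and 5 were called with the length trend removed. Pcsk1n, an inhibitor of a prohormone convertase, stood at 1.61 ± 0.08, Ptprn at 1.23 ± 0.14, Pam, which amidates peptides, at 1.18 ± 0.24 and Chgb, a granin, at -0.76 ± 0.15 in the authors' deposited table.

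Receptor and channel genes mostly did not pass the test. Of 43 peptide and hormone receptor genes 5 were higher and 5 lower in the authors' deposited table, against 4 and 5 adjusted over the list alone (median -0.16, percentile 52.9; -0.02 with the length trend removed), with the neurotensin receptors Ntsr1 at 1.62 ± 0.50 and Ntsr2 at -1.30 ± 0.19. Of 30 monoamine and acetylcholine receptor genes 1 was higher and 4 lower, against 1 and 0 adjusted over the list alone (median -0.76, percentile 1.51, and 3.94 against lists of like transcript length). After removal of the length trend the median was -0.49, with 1 called higher and 2 lower. The single higher one was Drd2, a dopamine receptor, at 1.77 ± 0.28 in the authors' deposited table, where Drd1 stood at -4.67 ± 1.61. Of 28 voltage-gated and pacemaker channel genes 1 was higher and 7 lower, also 1 and 7 adjusted over the list alone (median 0.04, percentile 69.7; 0.24 with the length trend removed), including the potassium channel Kcna2 at -1.54 ± 0.16 in the authors' deposited table. The higher one, outside the naming rule, was Cacna1b at 1.41 ± 0.44 in the authors' deposited table. Of 12 TRP channel genes 1 was higher and 2 lower, also 1 and 2 adjusted over the list alone (median -0.26, percentile 43.2; -0.03 with the length trend removed), namely Trpm4 at 1.89 ± 0.49, Trpc1 at -2.17 ± 0.61 and Trpm3 at -1.41 ± 0.36 in the authors' deposited table.

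Of 11 immediate early genes, which respond to neuronal activity, 3 were lower in the authors' deposited table, also 3 adjusted over the list alone (median -0.33, percentile 33.1). Arc stood at -1.34 ± 0.32 and Egr1 at -1.12 ± 0.32, the latter not called with the length trend removed, and Npas4, with no read in the immunoprecipitates, was at least 52.0-fold lower by the authors' deposited table. The Npas4 bound covers counting error only.

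Ribosomal protein genes and mitochondrial transcripts moved in opposite directions. Of 87 tested ribosomal protein genes the authors' deposited table called 84 higher and 0 lower, and 85 were higher adjusted over the list alone, with a median of 1.61 at percentile 100. Apart from Rpl10a, Rpl41 stood at 2.67 ± 0.10 and Rpl19 at 1.90 ± 0.10 in the authors' deposited table. Many of these genes have pseudogene copies that can share reads. With the length trend removed, Rpl41 was at 0.98 and Rpl19 at 0.28, the median was 0.32, 65 of 87 were above 0, and 42 were called higher and 4 lower. All 13 protein genes of the mitochondrial genome were lower in the authors' deposited table, as were all 13 adjusted over the list alone (median -2.22, percentile 0), with mt-Cytb at -2.50 ± 0.10 and mt-Co1 at -2.21 ± 0.09. Their median was -3.62 with the length trend removed, and all 13 were called lower. From the list of nuclear and long noncoding RNAs the table used here has 1 of 12 genes, Snhg11, at 0.19 ± 0.14, not called in the authors' deposited table or, with 0 calls, adjusted over the list alone. It was at 0.56 and called higher with the length trend removed.

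The 12 largest called folds towards the immunoprecipitates were genes of low level. Their means ranged from 50.5 to 641.0 normalized counts in the authors' deposited table, and 6 of them had no read in total RNA. Besides Nms these were Exosc6, a subunit of the RNA exosome, at least 925-fold higher, Slpi, a protease inhibitor, at least 111-fold, Cldn7, a tight junction protein, at least 89.7-fold, Hist1h2bk at least 79.8-fold and Ighg1, an immunoglobulin heavy chain, at least 74.5-fold, by the authors' deposited table. Exosc6 had the widest standard error of the 12, and an adjusted p of 0.00597 in the authors' DESeq2 test. The at-least folds cover counting error only and leave out the spread between libraries. The others of the 12 were Tmem45b, with a ratio of 205 (counting interval 43.6 to 9716), Cldn2, with a ratio of 84.7 (20.7 to 300), and, in log2 folds of the authors' deposited table, Gkn1 at 7.24 ± 1.30, Rspo4 at 7.23 ± 0.90, Hist1h2ai at 7.09 ± 1.33 and Ighv1-61 at 6.56 ± 1.55 (4.19 with the length trend removed). The counting intervals are those of unscaled reads and leave out the spread between libraries. Histone and immunoglobulin variable genes belong to families whose members share reads, so that these values are uncertain.

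The 12 largest called folds in the other direction all had no read in the immunoprecipitates. They were Dnali1, a dynein light chain of cilia, Cyp4f14, a cytochrome, Mr1 and H2-DMb1, which serve antigen presentation, Ush1g, Inpp5d, a phosphatase of blood cells and microglia, Sapcd2, Apol9a, Lad1, Abca9, Crb1 and Spag16. By the authors' deposited table they were lower by at least 98.6-fold (Crb1) to at least 232-fold (Dnali1), at means from 80.3 to 188.7 normalized counts. These bounds too cover counting error only, not the spread between libraries. In all, 234 tested genes had no read in the immunoprecipitates and 49 had none in total RNA.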

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

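The tests with centred folds, with the length trend removed, with the t distribution, without ribosomal protein, mitochondrial and pseudogene rows and with lists matched on length were chosen after the results were seen. No paired analysis was possible because the table holds the authors' comparison and no values per library. For the same reason leaving out each replicate, other normalizations, other count tests, other pseudocounts and set tests with an estimated correlation were not run. Counts of higher and lower genes stayed within 1.5 times of 2672 and 2653 under both filters, at an adjusted p under 0.01, with centred folds, without the length trend and without the named rows. With at least a 2-fold difference they were 1628 and 1658, which follows from the added threshold. With a t distribution of 2 degrees of freedom as the reference for the deposited folds and standard errors, 0 genes were higher and 0 lower after adjustment. Under it 1471 higher and 949 lower genes had an unadjusted p under 0.05, and Cck, still at 5.76, had an adjusted p of 0.307, the smallest of any gene; this reference left the threshold out of reach and says nothing about the stability of single calls. Without the length trend 1521 of the higher and 1799 of the lower genes kept their call, 72 higher genes became lower, and among the 128 named genes 1 called gene turned, Sst at -0.23, 3 uncalled genes changed sign (Ache, Slc17a6 and Hoxc4), 8 lost and 8 gained a call; the cause was not tested. Of 26 lists 13 were called, and 14 under each filter (of 25 with the stricter one) and with matched lengths. Depth limits the 2249 tested genes with means under 50, whose median standard error was 2.78 against 0.24 for means of at least 1000.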

Other observations

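The respiratory chain and Edinger-Westphal lists, the abundant genes and the test of counting noise were chosen after values were seen; the immunoglobulin, antibody-secreting cell and epithelial lists were drawn up after genes of these kinds were seen among the largest folds, and the choroid plexus list after Otx2 and Prlr were seen. The remaining tests of explanations were written before their results, and conditions added to them later are named.

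Nuclear genes of the mitochondrial respiratory chain were mostly higher in the immunoprecipitates, though not with the length trend removed. Of 86 tested, 68 were higher in the authors' deposited table, 4 lower and 14 did not pass, with a median of 1.55 at percentile 100 of random lists of like level; with the length trend removed the median was 0.02, with 30 called higher and 15 lower. Ndufa4 stood at 1.83 ± 0.09 and Uqcrh at 1.87 ± 0.10, against Sdha at -0.76 ± 0.09 in the authors' deposited table; with the length trend removed the first pair stood at 0.77 and 0.32. Among abundant genes outside the lists, Apobec3, a cytidine deaminase that restricts retroviruses, stood at 6.15 ± 0.18, Spint2, a protease inhibitor, at 2.95 ± 0.15, Sncg at 2.44 ± 0.16 and Resp18, a protein of endocrine secretory granules, at 2.22 ± 0.09 in the authors' deposited table, the last pair at 0.95 and 0.60 with the length trend removed. Lars2, a mitochondrial leucyl-tRNA synthetase, stood at 2.37 ± 0.08 with a mean of 129229 normalized counts in the authors' deposited table. That mean lies far above the median of 974 for genes with an adjusted p-value. Whether all of its reads came from Lars2 mRNA was not tested. Sparcl1 at -2.58 ± 0.09 and Trf, the transferrin gene, at -2.36 ± 0.09 were lower in the authors' deposited table.

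A list of genes of the peptide neurons of the Edinger-Westphal nucleus, which lies in front of the dorsal raphe, had 4 of 6 genes higher in the authors' deposited table (median 2.5, percentile 100). All but Nucb2, at 0.70 ± 0.38 (0.23 with the length trend removed) and not called, had been seen, and Ucn, Cartpt, Tac1 and Nmb are also in the peptide list, so that the count is no independent evidence of these cells. The choroid plexus list had 1 of 6 genes called, Clic6 at -4.79 ± 1.19 in the authors' deposited table (median -0.16, percentile 56.6).

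Genes with short transcripts were higher in the immunoprecipitates. Across the 8053 genes with a mean of at least 1000 and a known length, Spearman's rho of fold and transcript length was -0.47, and across all 16282 it was -0.28; genes are not independent replicates. Length of the longest annotated transcript as the whole cause is argued against for ribosomal protein genes. Their median of 1.61 lay at percentile 100 of random lists matched on level and length, among which the middle list already stood at 1.19. With the trend removed 65 of 87 genes stayed above 0, though these genes can share reads and are not independent counts. The expressed transcript need not be the longest one, so that for these genes the length of expressed transcripts stays open. Length as the whole cause is also argued against for astrocyte and oligodendrocyte genes, at percentile 0 and below 0 in 24 of 24. For the respiratory chain genes the tests part: their median lay at percentile 99.86 of matched lists, past the bound set beforehand, yet with the trend removed, a condition added later, it was 0.02 with 44 of 85 above 0, so that length cannot be told apart from an effect on these genes. No biological explanation was tested.

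Some genes of an immunoglobulin and of an epithelial list were higher in the immunoprecipitates. Of 9 immunoglobulin constant region genes 3 were higher and 6 did not pass, with Ighg2b at 5.76 ± 1.26 and Igkc, a light chain gene, at 1.10 ± 0.66 (-0.87 with the length trend removed) in the authors' deposited table; as 3 of the 9 had no read in a group and the list followed from genes already seen, its median is not read as evidence. RNA of antibody-secreting cells, epithelial cells or dividing cells could be a source, and medians of their markers were -1.56 (11 genes, 2 higher and 1 lower by call, percentile 5.1), 0.80 (7 genes, 3 and 1, percentile 94.5) and -1.78 (15 genes, 0 and 3, percentile 1.6). Over members with a mean of at least 50 the medians were 0.59 (6 genes, percentile 88.2), 2.69 (4 genes, all above 0, percentile 100) and 0.27 (7 genes, percentile 82.5), so that the first and last, below 0 over all members as set beforehand against these sources, turn, and the epithelial list passes the limit it missed. As the epithelial list also followed from genes already seen among the largest folds, its percentile is not read as evidence. With the genes of each list redrawn, a step added after the values were seen, the 95% intervals of the medians were -3.52 to 1.20, -4.09 to 3.11 and -3.46 to 0.27, so that all 3 sources stay open.

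Cartpt, Ucn and Tac1 had wide standard errors for their level, with deposited values 250, 39.1 and 37.0 times what counting their derived reads alone gives, while genes with a mean of at least 1000 exceeded that by a median of 9.1 times. Each also lay above all of the 100 genes nearest to it in counting error, whose largest standard errors were 0.138, 0.234 and 0.209. As the 3 genes were picked for wide standard errors, that rank adds no evidence. The size of the ratios to counting error argues against counting noise as the cause. Uneven capture of peptide-rich cells between the immunoprecipitates may be a cause. It was tested on all 81 abundant genes with a standard error above the 99th percentile for their level. Of these, 27.2% (95% Wilson interval 18.7 to 37.7) were higher in the immunoprecipitates against 50.8% of other genes. The interval treats genes as independent, though all rest on the same 4 libraries, and may be too narrow. The share meets the bound set beforehand against uneven capture. That bound was ill chosen, because 3 of the 81 are peptide genes, so that the set dilutes the pattern; without values per library the cause stays open.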
